A study of Mus musculus with 2 samples.

How the data were processed

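Abdominal aorta of mice given PPE was digested with collagenase I and DNase I, red cells were lysed, and single cells were captured on the BD Rhapsody system, per the labels' protocols. Each library was deposited as a matrix of whole-number UMI counts per gene and barcode, with lists of 31253 features and of barcodes, and these deposited counts were not normalised. That they are UMIs rather than reads follows from the platform and STARsolo and is not stated in the labels. The submitters' processing notes name CASAVA 1.8, STARsolo and the mm10 build, with no role or order given, and the gene annotation is not given in the sources used here. No cell annotation was used here. The lowest total per barcode was 500 UMIs in both libraries, so a minimum had been applied before deposit. Of the feature IDs, 31107 were found in the GENCODE M21 annotation of the same build, which supplied positions. Symbols shared by several IDs were kept apart by ID.

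Cells were kept with at least 500 UMIs, at least 250 genes and at most 25% mitochondrial UMIs. Scrublet was run per library at its automatic threshold and marked 0 of 7619 WT and 1 of 8784 Gsdme-KO cells. A caller that marks so few of so many cells has not worked, so doublets remain in the data. The 5% of cells with the highest Scrublet scores were therefore left out in an alternative. Kept cells (16402) were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave 27 clusters. No batch integration was used. Clusters were named "X-like" from 26 marker lists where at least 3 markers were detected in at least 25% of cells. A cluster stayed unnamed where its median UMI count was far under that of its library and none of the class's markers led it. Cluster leading genes were the 10 with the highest fold over all other cells after adding 5 CPM, and they are not reported as results. Macrophage clusters were compared by number, because cluster 3 had a lymphatic marker and no macrophage marker among its 10 leading genes.

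Counts were summed per class and library and expressed as CPM, and ratios of Gsdme-KO over WT carry exact conditional binomial intervals. With 1 library per group no test was run. Shares carry exact binomial (Clopper-Pearson) intervals and sums exact Poisson intervals at the 95% level. Classes needed at least 100 cells in each library. Genes were named by size: at least 50 UMIs and 5% of cells in the higher library, at least 10% of the CPM of the highest group, and a ratio of at least 1.5. They were ranked by the interval end nearest 1, taking 10 each way in fibroblast-like cells and 5 each way elsewhere. Gsdme was reported in every class first. The rule also set 10 each way for a macrophage class and an SMC class, which failed the marker check and the cell minimum. Gene models, ribosomal, mitochondrial, haemoglobin, receptor segment and sex linked genes were excluded. Sost and Npnt were left out as leading genes of the SMC-like cluster. The text names part of the 130 genes this gave.

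For 38 gene lists the median log2 ratio was taken over members with at least 10 CPM and 30 UMIs, for lists with at least 4 such members, and placed among 10000 random lists matched in 20 expression bins. Of the 521 list genes 513 matched a feature. A member with 0 UMIs in 1 library was set at 3 counts. Of 423 pairs of list and class, 72 lay below percentile 1 and 62 above percentile 99. Intervals of list medians came from 400 Poisson redraws. The groups, marker and gene lists, naming rule, measures and most alternatives were chosen before the data were examined. Comparing macrophage clusters by number and SMC-like cells with under 100 WT cells was chosen after.

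Tests on simulated counts drawn from the real sums changed 200 genes by known folds. In fibroblast-like cells the interval covered the true ratio for 95.7% of 8327 genes, and 100% of genes changed 1.5-fold had an interval on the right side of 1. In macrophage cluster 3 coverage was 95.5% of 7600 genes and 94.0% of genes changed 1.5-fold were on the right side. In endothelial-like cells coverage was 96.0% of 7451 genes, and 44.8%, 81.8% and 97.0% of genes changed 1.5, 2 and 4-fold were on the right side. Of 200 unchanged lists of 12 genes, 2.00% in fibroblast-like and 1.00% in endothelial-like cells lay below percentile 1 or above 99. These draws hold counting error alone, and their lists were genes picked at random. They do not show how often lists whose members vary together reach such percentiles.

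Alternatives were at least 1000 UMIs per cell, at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, thinning to 1000 UMIs, TMM factors from edgeR, median-of-ratios factors, the mean over cells, and no floors. Added after the data were seen were leaving out the highest doublet scores, clustering without SMC genes and fibroblast-like cells without the shallow cluster 9. Python 3.11.15 was used with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.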

Results

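Single-cell RNA profiles were collected from the abdominal aorta of mice in which an aneurysm had been induced by infusion of porcine pancreatic elastase (PPE), an enzyme that degrades elastin. The comparison asked how cells of the aneurysmal aorta differ when Gsdme is deleted throughout the body. Gsdme encodes gasdermin E, a protein that forms pores in the plasma membrane after cleavage by caspase 3. The control library (WT) came from C57BL/6J mice and the other library (Gsdme-KO) from mice with the deletion. There was 1 library per group, and the number of mice behind each library was not given in the sources used here. The WT library held 7736 barcodes and 38988898 UMIs (unique molecular identifiers, each counting 1 captured transcript), and the Gsdme-KO library held 9034 barcodes and 52532964 UMIs. After the cell filter 7619 WT and 8783 Gsdme-KO cells were kept, with medians of 3835 and 4060 UMIs and 1755 and 1805 genes per cell. The median share of mitochondrial UMIs was 2.81% in WT and 3.55% in Gsdme-KO. No difference below has a replicate check and none was tested. All intervals are 95% intervals that cover counting error only, so they describe these 2 libraries and not the conditions.

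Gsdme (ENSMUSG00000029821, chromosome 6, 50188888 to 50263862, minus strand, mm10) had the lower level in the library labelled Gsdme-KO. Over all kept cells it stood at 5.53 CPM in WT (Poisson interval 4.82 to 6.32, 215 UMIs) and 2.55 CPM in Gsdme-KO (2.13 to 3.02, 133 UMIs), a ratio of 0.461 (0.369 to 0.575). Of the classes compared, neutrophil-like cells held the highest level in both libraries, with 22.8 CPM in WT and 10.8 CPM in Gsdme-KO. In fibroblast-like cells Gsdme stood at 3.62 CPM in WT and 0.973 CPM in Gsdme-KO (ratio 0.269, 0.143 to 0.492). Among macrophage clusters the levels were 5.59 and 3.87 CPM in cluster 2, 1.99 and 0.202 CPM in cluster 3, and 6.01 and 1.70 CPM in cluster 7. The interval of the ratio held 1 in cluster 2 (0.693, 0.382 to 1.21). The lower level was not seen in monocyte-like cells (5.74 and 6.57 CPM, ratio 1.14, 0.609 to 2.19), T cell-like cells (5.91 and 5.61 CPM) or dendritic-like cells (2.53 and 5.55 CPM, ratio 2.19, 0.547 to 12.6), where no difference was detectable at this depth. B cell-like, platelet-like and endothelial-like cells held at most 3 UMIs of Gsdme in either library, and SMC-like cells (SMC, smooth muscle cell) held none. A UMI of Gsdme was held by 2.43% of WT cells (2.09 to 2.80) and 1.13% of Gsdme-KO cells (0.917 to 1.37), and no class known to lack the gene was at hand to give a background. After each cell was thinned to 1000 UMIs the ratio over all cells was 0.737, and as a mean over cells it was 0.617. The deleted part of the gene is not given in the sources used here, and 3' tags outside it check nothing, so the remaining signal does not decide the genotype. The annotated span of Mpp6 overlaps that of Gsdme, so UMIs from the shared part are uncertain.

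**Figure D1:**
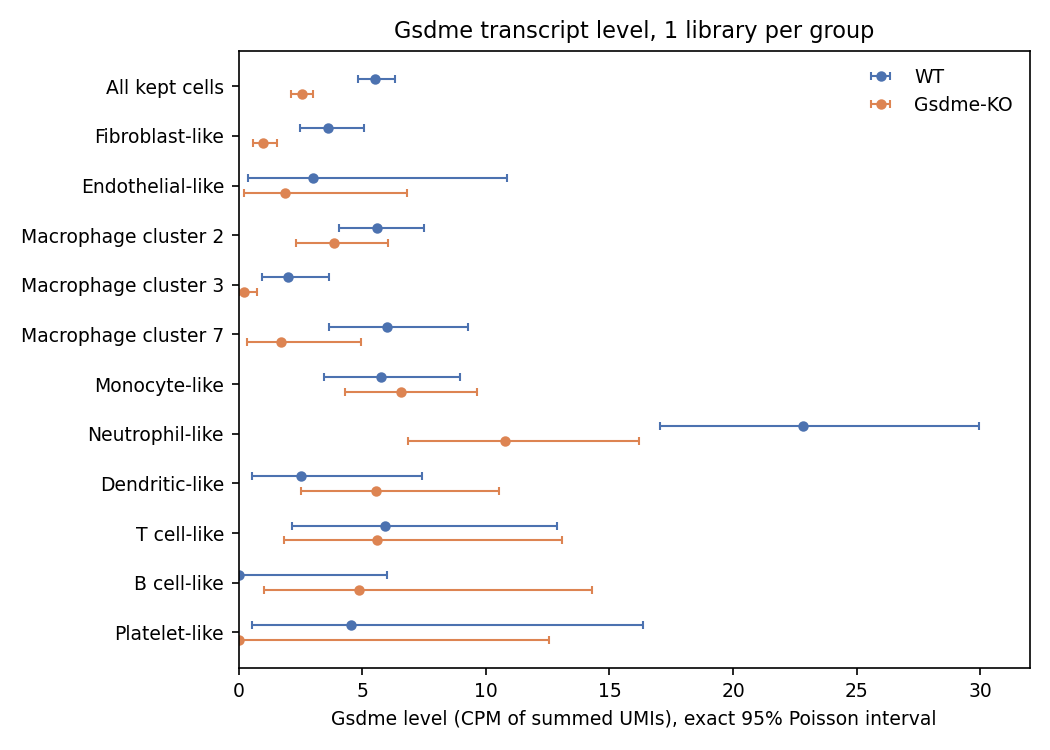
Gsdme level in CPM of summed UMIs on the horizontal axis, for all kept cells and each class or cluster, with points for the WT and the Gsdme-KO library and bars for exact 95% Poisson intervals. Neutrophil-like cells reach 22.8 CPM in WT and 10.8 CPM in Gsdme-KO, and monocyte-like cells show 5.74 and 6.57 CPM.

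The share of each cell class was compared next. Cells of the non-immune classes (fibroblast, smooth muscle, endothelial, lymphatic endothelial, mesothelial and adipocyte-like) made up 18.6% of WT cells (17.7 to 19.5) and 27.2% of Gsdme-KO cells (26.3 to 28.2), a ratio of 1.46 (1.37 to 1.56). Fibroblast-like cells accounted for most of them, with 15.3% in WT and 21.9% in Gsdme-KO (ratio 1.44, 1.34 to 1.55). Within the non-immune classes the fibroblast-like share was 82.1% in WT and 80.6% in Gsdme-KO. Macrophage cluster 2, led by Trem2, Gpnmb and Spp1, held 13.3% of WT and 7.57% of Gsdme-KO cells (ratio 0.569, 0.516 to 0.629). Macrophage cluster 7, led by Cd72 and Slamf9, held 7.40% and 3.27% (ratio 0.441, 0.382 to 0.510). Macrophage cluster 3, led by Lyve1, Fcna and Cd163, which mark tissue-resident macrophages, held 8.49% of WT and 11.5% of Gsdme-KO cells (ratio 1.35, 1.22 to 1.49). The smaller macrophage cluster 19 held 1.22% and 2.12% (ratio 1.73, 1.35 to 2.25), and cluster 21 held 1.31% and 1.08% (ratio 0.824, 0.616 to 1.10).

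Neutrophil-like cells made up 16.8% of WT and 14.3% of Gsdme-KO cells (ratio 0.849, 0.785 to 0.919), and within the immune classes their shares were 25.2% and 25.1%. Of their 2 clusters, cluster 1 had a ratio of 0.725 (0.660 to 0.796) and cluster 8, led by S100a9, S100a8 and Mmp8, of 1.27 (1.09 to 1.47). T cell-like cells made up 4.34% and 3.40% (ratio 0.784), B cell-like cells 2.89% and 2.08% (ratio 0.722), and platelet-like cells 2.81% and 1.83% (ratio 0.653). The intervals of the ratio held 1 for monocyte-like cells (7.72% and 7.58%, although the ratio was 1.26 with at least 1000 UMIs per cell), dendritic-like cells (3.03% and 3.39%) and endothelial-like cells (1.65% and 1.84%). Within the immune classes monocyte-like shares were 11.6% (10.7 to 12.5) and 13.4% (12.4 to 14.4). Dendritic-like shares were 4.55% (3.99 to 5.15) and 5.98% (5.34 to 6.68), with intervals that did not overlap. T cell-like shares there were 6.51% (5.85 to 7.23) and 6.00% (5.36 to 6.70). B cell-like shares were 4.33% (3.79 to 4.93) and 3.67% (3.17 to 4.24), so the intervals of both overlapped. The 2 dendritic-like clusters stood apart, with a ratio of 1.29 (1.06 to 1.56) for cluster 14 and of 0.424 (0.243 to 0.721) for cluster 24, which was led by Ccr7, Ccl22 and Il12b. The SMC-like cluster counted 61 WT and 175 Gsdme-KO cells. Its leading genes themselves differed between the libraries, so its share was compared after clustering without them, a choice made after seeing the data, where the ratio was 2.13 (1.61 to 2.85). It was 2.49 in the clustering used elsewhere and 3.60 with each library clustered on its own. When each library was clustered on its own, no Gsdme-KO cluster matched cluster 7. Clusters 11, 12, 13 and 16 stayed unnamed because their cells were shallow and none of the markers of their best class was among their leading genes. They held 3.12%, 3.61%, 2.61% and 2.55% of WT cells and 4.14%, 3.60%, 4.18% and 2.33% of Gsdme-KO cells.

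**Figure D2:**
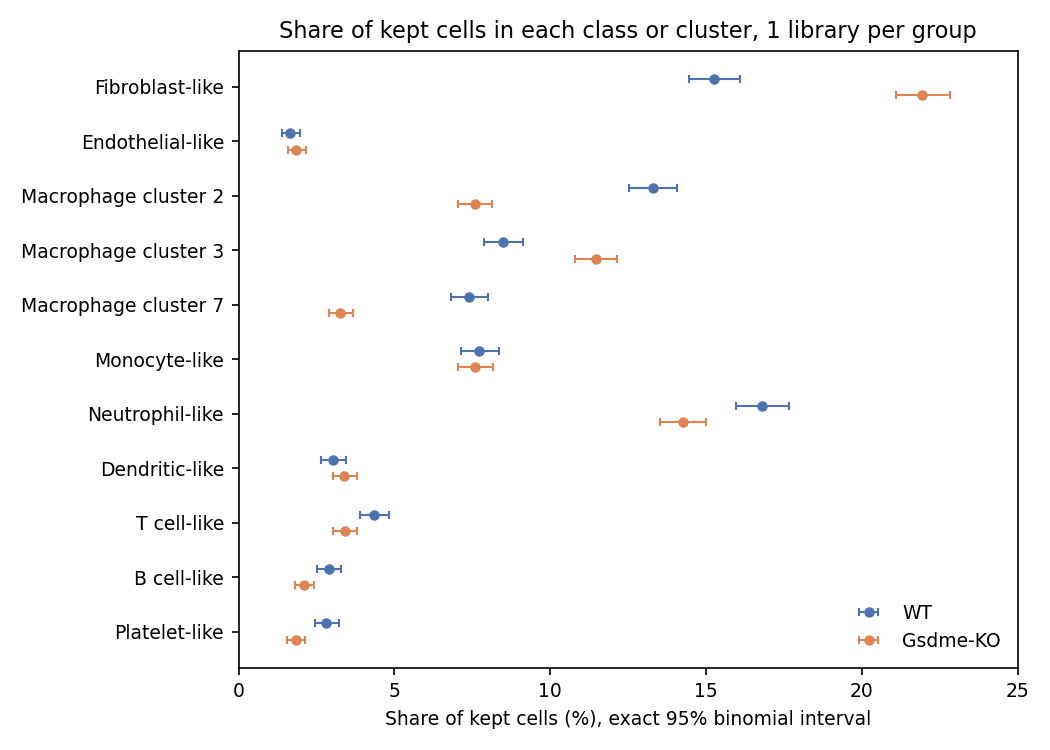
Share of kept cells in percent on the horizontal axis for each class or cluster, with points for the WT and the Gsdme-KO library and bars for exact 95% binomial intervals. Fibroblast-like cells stand at 15.3% in WT and 21.9% in Gsdme-KO, and macrophage cluster 2 at 13.3% and 7.57%.

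Levels of single genes were compared within fibroblast-like cells. Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131, X, 20870166 to 20874735), stood at 104 CPM in WT and 465 CPM in Gsdme-KO, a ratio of 4.48 (4.19 to 4.80). The interleukin 6 family cytokines Lif (27.4 and 122 CPM, ratio 4.44) and Il11 (13.7 and 63.7 CPM, ratio 4.65) and the epidermal growth factor receptor ligand Ereg (25.4 and 89.0 CPM, ratio 3.50) were also higher. The transcription factor gene Egr4 had the largest ratio among the named genes of this class, with 2.41 CPM in WT and 55.6 CPM in Gsdme-KO (ratio 23.1, 15.2 to 37.0). Esm1, Ahsg, Col28a1, Ccl19 (ENSMUSG00000071005) and Ap4e1 completed the 10 higher genes, with ratios of 7.10, 5.72, 6.31, 3.68 and 3.08. Among the 10 lower genes Igfbp3, which binds insulin-like growth factors, stood at 124 CPM in WT and 32.7 CPM in Gsdme-KO (ratio 0.263, 0.238 to 0.290). The lymphatic growth factor gene Vegfc stood at 22.5 and 5.95 CPM (ratio 0.265), and the imprinted genes H19, Mest and Zim1 had ratios of 0.280, 0.255 and 0.252. H19 was held by 7.91% of WT and 6.90% of Gsdme-KO cells, so its ratio rests on few cells. The same holds for Egr4 (0.430% and 6.54%), Mest (6.79% and 3.43%) and Zim1 (5.25% and 2.91%). It also holds for Col28a1 (1.46% and 6.59%), Esm1 (2.24% and 8.25%) and Lyrm7 (6.36% and 1.61%). Il11 was held by 2.67% of WT and 12.8% of Gsdme-KO cells, and Ereg by 3.96% and 10.3%. Nmnat1, Tpm3-rs7, Wdfy1, Inmt and Lyrm7 had ratios of 0.102, 0.161, 0.212, 0.223 and 0.177. Tpm3-rs7 carries the name of a tropomyosin-related sequence, so its count is uncertain where UMIs could be split with a close copy. Fibroblast cluster 22 made up 92 of 1163 WT and 84 of 1927 Gsdme-KO cells of this class, and levels over the class were not separated from such shifts.

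**Figure D3:**
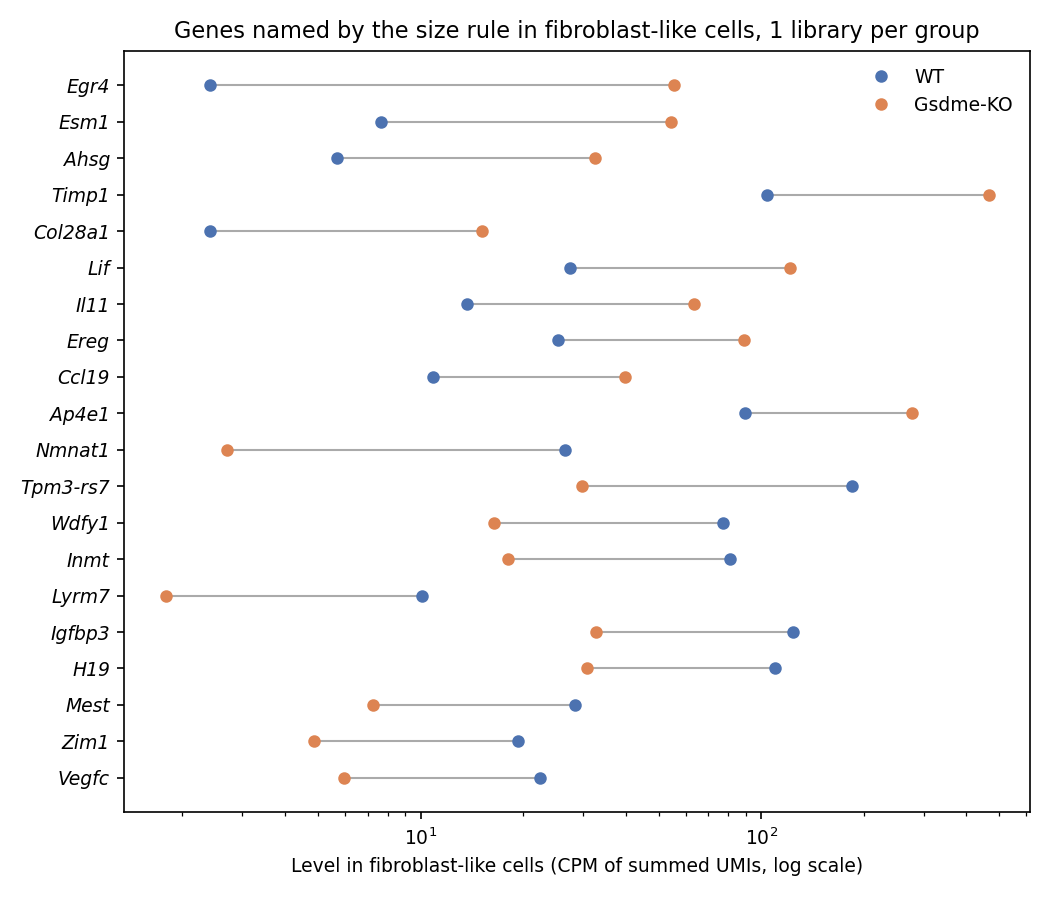
Level of the 10 higher and 10 lower named genes in fibroblast-like cells, in CPM of summed UMIs on a log axis, with 1 point for the WT library and 1 for the Gsdme-KO library joined by a line. Timp1 lies at 104 CPM in WT and 465 CPM in Gsdme-KO, and Igfbp3 at 124 and 32.7 CPM.

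Gene lists fixed before the data were examined described fibroblast-like cells further, each with its percentile among 10000 random lists matched on expression. The median log2 ratio over all measured genes of this class was -0.11, and list medians are read against it. In the elastic fibre list 15 of 19 members were higher in Gsdme-KO, with a median log2 ratio of 0.27 (percentile 99.9, 0.23 to 0.44 over the alternatives). Emilin1 stood at 22.6 and 33.1 CPM, whereas Ltbp4 stood at 354 and 252 CPM. The protease inhibitor list had a median of 0.41 (percentile 99.6, 6 of 9 members higher), with Serpina3n at 431 and 748 CPM and Timp2 at 4038 and 3019 CPM. The protease list had a median of -0.26 (percentile 0.35, 12 of 16 lower), with the stromelysin-3 gene Mmp11 at 90.6 and 31.6 CPM and Mmp19 at 107 and 150 CPM. The collagen list stayed near the class median, at -0.09 (percentile 18.8), with Col3a1 at 12843 and 14366 CPM and Col14a1 at 3217 and 2414 CPM. The chemokine list had a median of 0.33 (percentile above 99.9, 11 of 18 higher), and Ccl2, a monocyte attractant, stood at 766 and 2142 CPM. The complement list had a median of -0.42 (13 of 14 lower, -0.52 to -0.26 over the alternatives), but 6 of its 14 members, such as C1qb and C3ar1, lay below 10% of their level in the highest group.

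Proliferation genes were higher in fibroblast-like cells of the Gsdme-KO library. The cell cycle list had a median log2 ratio of 1.20 (11 of 13 members higher), with Ube2c at 3.40 and 27.3 CPM and Cdk1 at 4.38 and 22.2 CPM, while Mcm3 stood at 11.4 and 10.5 CPM. Only 2 of these 13 members reached 10% of their level in the highest group. After thinning to 1000 UMIs, at least 2 of 10 cycling genes were seen in 3 of 1025 WT cells (0.293%, 0.0604 to 0.853) and in 41 of 1732 Gsdme-KO cells (2.37%, 1.70 to 3.20), leaving out 138 and 195 shallower cells. Without thinning the shares were 2.67% and 6.43%. With 1 gene enough, the thinned shares were 3.61% and 5.37% (ratio 1.49), under the 6.64% and 6.16% of neutrophil-like cells. Among neutrophil-like cells, which are post-mitotic, the thinned shares at 2 genes were 0.262% and 0.184%, at unthinned medians of 1654 and 1566 UMIs per cell against 7224 and 8224 in fibroblast-like cells. The WT fibroblast-like share was close to that background. Free RNA from cycling cells of other classes was not excluded.

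The interferon lists had lower medians in the Gsdme-KO library in several cell classes. The type I interferon list had a median log2 ratio of -0.80 in neutrophil-like cells (15 of 16 members lower), -0.70 in macrophage cluster 2 (15 of 15), -0.64 in cluster 3 (19 of 22), -0.46 in cluster 7 (20 of 22), -0.46 in dendritic-like cells (16 of 20) and -0.34 in fibroblast-like cells (14 of 19), each at or below percentile 0.21. The fibroblast-like value was -0.18 with TMM factors and -0.19 with size factors, the dendritic-like value -0.95 after thinning and the neutrophil-like value -0.54 with at least 1000 UMIs per cell. The antiviral gene Ifit3 stood at 60.6 CPM in WT neutrophil-like cells and at 12.7 CPM in Gsdme-KO. At least 3 macrophage markers were seen in 70.0% of WT and 48.9% of Gsdme-KO fibroblast-like cells, in 30.9% and 18.8% of neutrophil-like cells and in 59.3% and 42.3% of dendritic-like cells, so carried-over macrophage RNA was not excluded there. In neutrophil-like cells 35.8% of the log2 ratio remained without the 5% of cells richest in list UMIs, and 24.0% where the cells were chosen for each gene by the other members, a choice made after the result was seen. In macrophage cluster 3 Ifit1 stood at 120 and 51.6 CPM, while Ifi27l2a stood at 435 and 658 CPM. Monocyte-like cells had a median of -0.09 (percentile 32.9), B cell-like cells 0.16 and endothelial-like cells -0.27 (percentile 7.57). The interferon gamma list had a median of -0.51 in fibroblast-like cells, where 15 of 15 members were lower (-0.65 to -0.34 over the alternatives) and the immunity GTPase gene Irgm1 stood at 97.4 and 40.3 CPM. Its medians were -0.43 in cluster 3, -0.45 in dendritic-like cells and -0.46 in neutrophil-like cells, against -0.13 in monocyte-like cells (percentile 16.2), -0.035 in endothelial-like cells (percentile 61.0) and 0.22 in platelet-like cells (percentile 88.3). The MHC class I list, which presents peptides to CD8 T cells, had a median of -0.69 in fibroblast-like cells and -0.42 in cluster 3, with 10 of 11 members lower in each. Its light chain gene B2m stood at 1872 and 1905 CPM in fibroblast-like cells and at 3131 and 4778 CPM in cluster 3.

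**Figure D4:**
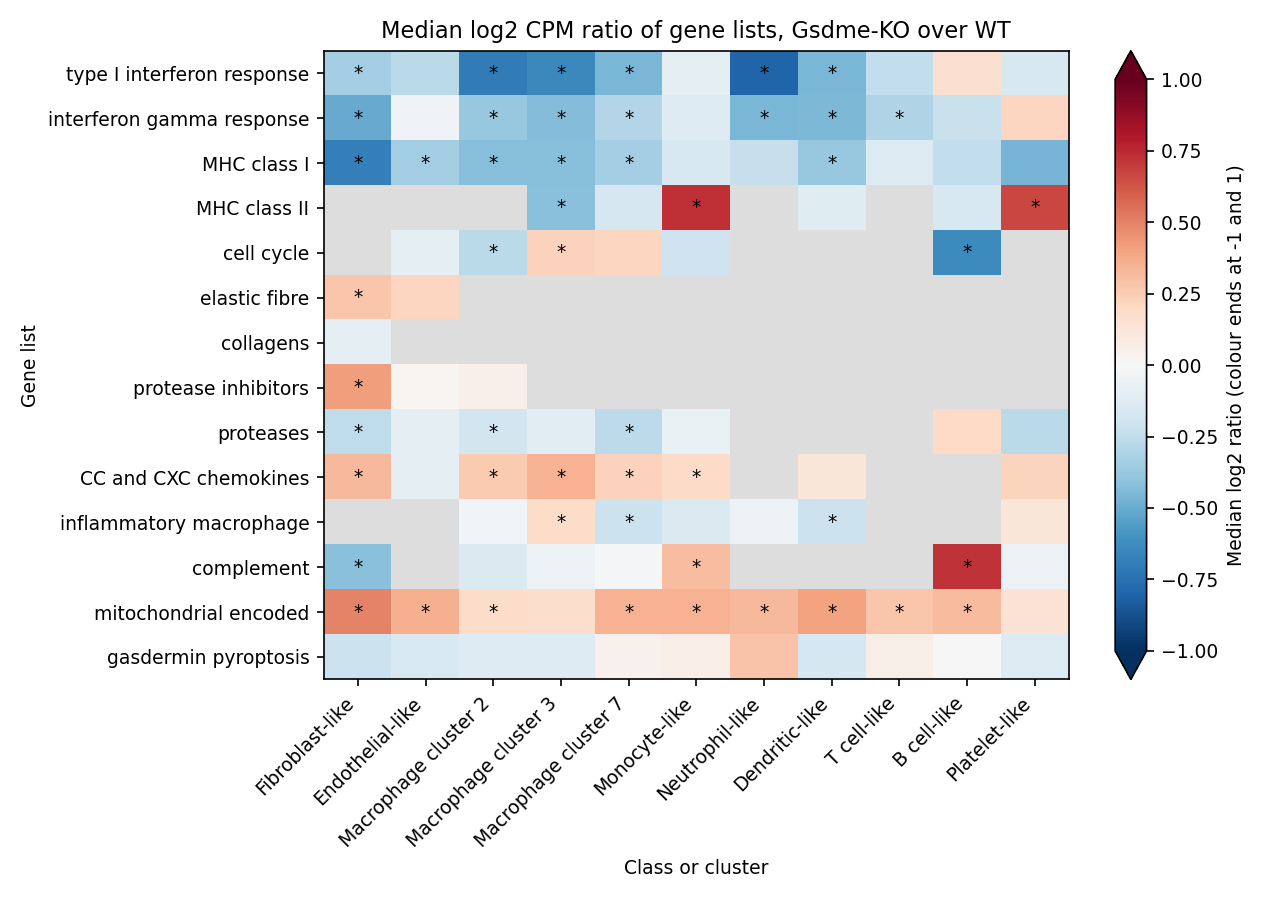
Median log2 CPM ratio (Gsdme-KO over WT) of 14 gene lists in rows for 11 classes and clusters in columns, with blue for lower and red for higher in Gsdme-KO. Stars mark percentiles below 1 or above 99 among matched random lists, and grey marks lists that were not measured or had under 50% of members above background. The type I interferon row shows medians from -0.80 in neutrophil-like cells to 0.16 in B cell-like cells.

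The myeloid cells differed between the libraries in further genes. In macrophage cluster 2 the prostaglandin-degrading enzyme gene Hpgd stood at 0.889 and 48.1 CPM (ratio 54.1, 25.9 to 136), Fcrls at 203 and 1056 CPM (ratio 5.19) and the growth factor gene Gdf3 at 3.94 and 27.7 CPM. In cluster 3 the acute-phase gene Saa3 stood at 155 and 730 CPM (ratio 4.71, 4.37 to 5.08). In the same cluster Timd4, a receptor for phosphatidylserine on dying cells, stood at 171 and 21.6 CPM (ratio 0.126), and Mmp9, a gelatinase, at 175 and 30.1 CPM (ratio 0.172). Mmp9 also led neutrophil-like cluster 1 and stood in cluster 3 at 13.2% of its level in the highest group, so carried-over RNA was not excluded. In cluster 7 no UMI of Hpgd was seen in WT against 84.8 CPM in Gsdme-KO. Monocyte-like cells had Ccl6 at 506 and 1644 CPM (ratio 3.25, 3.08 to 3.43) and the osteocalcin gene Bglap2 at 99.8 and 1.01 CPM (ratio 0.0101). The MHC class II list was higher in monocyte-like cells, with all 7 members higher and a median log2 ratio of 0.73, and lower in cluster 3, with all 7 lower and a median of -0.42. In the same monocyte-like cells the resident-type macrophage list had a median of 0.84 (9 of 10 higher), although 2 of its 10 members lay above background, so macrophage transcripts there also differed. The invariant chain gene Cd74 stood at 1999 and 2988 CPM in the former and at 4493 and 3099 CPM in the latter. The chemokine list had a median of 0.35 in cluster 3 (13 of 16 higher), with Ccl7 at 1124 and 2014 CPM. The monocyte value of the MHC class II list ran from 0.28 to 0.81 over the alternative settings.

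Neutrophil-like cells of the Gsdme-KO library had higher levels of Chil3 (21.1 and 111 CPM, ratio 5.27) and of the iron-binding granule gene Lcn2 (118 and 294 CPM, ratio 2.49), and lower levels of Depdc5 (497 and 165 CPM, ratio 0.332) and Atp11a (42.6 and 14.5 CPM). Pkd1l2, Sec22c and Pttg1 had ratios of 15.2, 17.3 and 4.27, and Vmn2r96 and Slc22a4 of 0.00667 and 0.212. Clusters 1 and 8 made up different parts of this class in the 2 libraries, as did clusters 14 and 24 of dendritic-like cells, so levels over either class were not separated from that shift. In dendritic-like cells Plac8 stood at 295 and 638 CPM and Timd4 at 399 and 69.1 CPM. The T cell-like cluster also carried markers of mast cells, natural killer cells and innate lymphoid cells: at least 3 NK markers were seen in 11.8% of WT and 10.7% of Gsdme-KO cells, and at least 3 ILC2 markers in 3.32% and 7.02%. In it Tnfsf8 stood at 71.9 and 239 CPM, the interleukin 2 receptor gene Il2ra at 148 and 305 CPM, the chemokine gene Ccl4 at 367 and 174 CPM and Ifit1 at 70.9 and 26.9 CPM. At least 3 macrophage markers were seen in 24.2% of WT and 14.7% of Gsdme-KO cells of this cluster and Ccl4, which also led macrophage cluster 7, stood in it at 13.7% of its level in the highest group, so carried-over RNA was not excluded. In B cell-like cells the macrophage genes Lyve1 (11.4 and 506 CPM), Mrc1 (101 and 717 CPM) and Ccl6 (113 and 1120 CPM) led the higher genes, although a UMI of Lyve1 was held by 8.20% of the Gsdme-KO cells. In platelet-like cells Itgbl1 stood at 18.1 and 214 CPM and Hacd4 at 1902 and 837 CPM.

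Vascular cells were fewer. In endothelial-like cells (126 WT and 162 Gsdme-KO) Igfbp5 stood at 176 and 516 CPM (ratio 2.94, 2.40 to 3.62), although 10.3% of WT and 9.88% of Gsdme-KO cells held it and it also led fibroblast cluster 6. At least 3 fibroblast markers were seen in 36.5% and 46.3% of the endothelial-like cells, so fibroblast RNA was not excluded. Others were the guidance gene Slit2 at 57.1 and 175 CPM, the activin antagonist Fst at 212 and 55.6 CPM (ratio 0.262) and Hmga2 at 125 and 12.2 CPM. The log2 ratios of Saa3, Slit2 and Slpi in this class turned negative under single alternatives. The haemoglobin list had a median log2 ratio of -5.82 in endothelial-like cells, where Hba-a1 stood at 287 and 4.71 CPM. At least 3 erythroid markers were seen in only 2 of 126 WT and 1 of 162 Gsdme-KO cells of this class. How the haemoglobin UMIs were spread over barcodes was not examined. The SMC-like cluster, compared although under 100 WT cells, a choice made after seeing the data, had a median log2 ratio of 0.60 for the contractile list (16 of 18 higher), with Ppp1r14a at 37.4 and 89.4 CPM and Actg2 at 128 and 103 CPM. Acta2, Tagln, Myh11 and Itga8 of that list also defined the cluster, so its median is not independent of the clustering. The elastic fibre list had a median of -0.31 in it (percentile 0.71, 12 of 16 lower), opposite in sign to fibroblast-like cells, a difference that was not tested. Mfap4 stood at 44.4 and 252 CPM, Mfap2 at 39.7 and 14.9 CPM and the protease gene Adamts8 at 30.4 and 342 CPM. Its collagen list had a median of -0.67 (12 of 15 lower), with Col15a1 at 1378 and 602 CPM and Col18a1 at 220 and 534 CPM. As a mean over cells the contractile median was 0.18, the collagen median -0.38 and the elastic fibre median -0.072.

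The list of transcripts encoded in mitochondria had medians above 0 in all 12 classes and clusters, from 0.14 to 0.50. It lay above percentile 99 in 10 of the 12. From 9 of 13 members in clusters 2 and 3 to 12 of 13 in SMC-like cells were higher in Gsdme-KO, and at least 1 member was lower in each class or cluster. The gasdermin and pyroptosis list stayed between -0.21 and 0.29, and its neutrophil-like value of 0.29 lay at percentile 98.8. The list of other death pathways ranged from -0.21 to 0.20, and oxidative stress from -0.22 to 0.21, with no percentile below 1 or above 99 in either. Medians of the unfolded protein response list lay below 0 in all 12 classes and clusters. They ran from -0.28 in T cell-like cells (0.062 after thinning) to -0.0076 in fibroblast-like cells, where the percentile was 51.9. Its medians lay below percentile 1 in 4 of the 12, among them monocyte-like cells (-0.27, percentile 0.11). Those of the TGF-beta and BMP list ran from -0.29 to 0.12. Medians ranged from -0.36 to 0.30 for immediate early genes of dissociation, and lay below 0 in 11 of 12 classes and clusters. They ranged from -0.40 to 0.61 for heat shock, -0.51 to 0.28 for hypoxia and -0.27 to 0.16 for glycolysis. Nuclear oxidative phosphorylation genes ranged from -0.25 to 0.12, senescence and p53 genes from -0.31 to 0.14, endothelial activation genes from -0.43 to 0.19 and phagocytosis genes from -0.30 to 0.11. The inflammasome list ranged from -0.49 to 0.56, the inflammatory macrophage list from -0.83 to 0.18, the list of cytokines and NF-kB targets from -0.42 to 0.26 and the lipid-associated macrophage list from -0.47 to 0.18. Alternative activation ranged from -0.65 to 1.52 and resident-type macrophage genes from -0.80 to 3.37, with the highest value of each in B cell-like cells. Under single alternatives the hypoxia value of 0.28 turned to -0.084, the heat shock value of 0.61 to -0.40, the lipid-associated value of 0.18 to -0.067 and the alternative activation value of -0.65 to 0.37. Neutrophil granule genes ranged from -0.74 to 0.47, T cell activation genes from -0.36 to 0.29 (the latter -0.18 at 1000 UMIs), SMC modulation genes from -0.26 to 0.40 (the latter -0.16 after thinning) and matricellular genes from -0.32 to 0.46. Some of these ends came from classes in which most members lay below 10% of their level in the highest group: fibroblast-like cells for the inflammatory and lipid-associated macrophage lists (4 of 14 and 7 of 18 members above), and both ends of the resident-type list (endothelial-like cells 1 of 9, B cell-like cells 4 of 11) and of the granule list (fibroblast-like cells 1 of 9, endothelial-like cells 2 of 9). The same held for the low end of the cytokine and NF-kB list in SMC-like cells (3 of 12) and, in T cell-like cells, for the low end of the phagocytosis list (2 of 13) and the high end of the matricellular list (1 of 6). The sex linked list lay between -0.027 and 0.47 in 10 classes and clusters.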

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

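The tests of genes shared across classes, of scaling and depth, of interferon-high cells and of the fibroblast share were chosen after their results were seen. Each pair of values that follows came from a list near the top of the matched random lists in 1 class or cluster and near the bottom in another, and the difference between the classes was not tested.

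The median log2 ratio of the MHC class II list was 0.73 in monocyte-like cells and -0.42 in macrophage cluster 3, and that of the inflammatory macrophage list was 0.18 in cluster 3 and -0.21 in cluster 7. Hypoxia genes stood at 0.28 in cluster 3, but at -0.084 there after thinning, and at -0.51 in SMC-like cells. The list of cytokines and NF-kB targets stood at 0.26 in endothelial-like and -0.28 in dendritic-like cells, where cluster 24, led by the list gene Il12b, had a share ratio of 0.424. Inflammasome genes stood at 0.56 in platelet-like and -0.49 in fibroblast-like cells, where the myeloid genes Il1b and Nlrp3 were lowest, 5 of 8 members lay above background and at least 3 macrophage markers were seen in 70.0% of WT and 48.9% of Gsdme-KO cells. Heat shock genes stood at 0.61 in platelet-like and -0.40 in T cell-like cells, with the platelet-like value at -0.40 without top doublet scores. The last lists were highest in B cell-like cells, which held macrophage transcripts: complement at 0.72 (-0.039 after thinning) against -0.42 in fibroblast-like cells, alternative activation at 1.52 against -0.65 in SMC-like cells (interval -0.99 to 0.40, and 0.37 without floors), and immediate early genes at 0.30 against -0.36 in SMC-like cells.

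The first pattern weighed is a set of 15 genes that differed at least 1.5-fold the same way in every class where they were measured (at least 6) and at least 2-fold in the median, 10 lower and 5 higher in Gsdme-KO. They include Tpm3-rs7 (348 and 47.5 CPM over all cells) and Nmnat1 (24.4 and 3.03 CPM). For 12 of them, set apart because it was over 10%, the median class held at least 16.9% of the CPM of the highest compared class. The fibroblast transcript Col3a1 held 1.28% in other cells. The bound of 10% was met by how the 12 were set apart, so meeting it is no test. Set against the Col3a1 value, their levels argue against free RNA from 1 of the compared classes. Free RNA stays open for Clec3b, Ctla2b and Gm47015. Clec3b at 1.26%, near the Col3a1 value, and Ctla2b at 2.47% lay under the 5% set for free RNA. Gm47015 stood at 6.61%, above that bound. Clusters that were not compared did not count here, so free RNA from 1 of those stays open. Gm15726 and Gm47283 were among the leading genes of unnamed cluster 16. Vmn2r96, the gene at 16.9%, stood in neutrophil-like cells at 32.6% of its highest group when other clusters also counted. DNA carried along with the Gsdme locus is argued against as a common source, as 0 of the 15 lie within 10 Mb of Gsdme. Genes measured in fewer than 6 classes are not covered by this. Inmt, named as lower in fibroblast-like cells (ratio 0.223), lies inside that window, from 55170626 on chromosome 6. Variants of the knockout line elsewhere in the genome may account for genes on 12 chromosomes, but line and library cannot be told apart here.

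The second pattern is the lower type I interferon list. Scaling and depth are argued against as the whole source. The median closest to 0 over 6 classes and clusters under TMM factors, size factors and thinning was -0.18. That was the fibroblast-like value with TMM factors, against -0.34 without them. Scaling may thus hold part of the difference in that class. A small group of interferon-high cells is argued against as the main source in the 5 classes and clusters other than neutrophil-like cells. There at least 63.9% of the log2 ratio remained without the 5% of cells with the highest share of list UMIs. At least 83.9% remained with cells chosen by the other members. In neutrophil-like cells 35.8% remained, and 24.0% where the cells were chosen for each gene by the other members. At least 84.8% remained in 200 draws with list UMIs spread over cells by depth, so such a group may hold most of the difference there. Less than in every such draw also remained in fibroblast-like cells (70.8%, lowest draw 87.6%) and dendritic-like cells (63.9%, lowest 85.7%). The same held for cluster 2 (84.9%, lowest 89.9%) and cluster 3 (80.2%, lowest 94.5%). Interferon-high cells may thus hold part of the difference in these. In cluster 7 the log2 ratio grew to 160% of its value. Whether loss of Gsdme or another difference between the libraries is behind the lower list cannot be told apart with 1 library per group.

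The third pattern is the higher fibroblast share. Among the fibroblast clusters, fewer immune cells raising every non-immune cluster alike is argued against only for cluster 22, the smallest and the lowest in ratio. It held 92 of 1163 WT and 84 of 1927 Gsdme-KO cells of the class. Its share ratio was 0.792 (0.582 to 1.08), against 1.44 (1.29 to 1.61) in cluster 4. Clusters 6 and 9 stood at 1.46 and 1.66, near cluster 4, so the explanation stays open for these 3, which held most cells of the class. Within the non-immune classes the fibroblast-like share was 82.1% in WT and 80.6% in Gsdme-KO. Cluster 4 held 36.6% and 36.2% of them and cluster 6 23.5% and 23.4%. Cluster 9 held 15.5% and 17.6%, and cluster 22 6.49% and 3.51%. Shallow or damaged cells are argued against, as the lower end of the interval stayed at 1.35 or above with at least 1000 UMIs or at most 10% mitochondrial UMIs. Digestion or dissection that released more of some cell types cannot be told apart from biology with 1 library per group, and the endothelial-like share ratio was 1.12.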

How the results depend on the processing

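No paired analysis was possible because each group has 1 library. The alternatives leaving out the top 5% of doublet scores, clustering without SMC genes, and dropping fibroblast cluster 9 were chosen after seeing the data. Of 114 alternative share ratios, none of a class whose interval lay apart from 1 reversed and 4 moved beyond the counting interval. The monocyte-like ratio of 0.983, whose interval held 1, lay on either side of 1. The 168 values of the 15 main list results kept their sign and 39 moved. Of 1302 values of other lists 24 reversed and 224 moved, and of 1300 values of named genes 4 reversed and 146 moved, 72 of them after thinning. Lists were checked here only where they lay below percentile 1 or above 99, so the stability of other pairs is not shown. Without floors 63 of 130 named genes were still named. The Gsdme ratio kept its direction in 9 of 9 alternatives. Keeping doublets added 1 cell, yet clustering again with it moved the monocyte-like MHC class II value, so the border of that class is unstable. No match was found for SMC-like cells at 10% mitochondrial or for cluster 7 at 1000 UMIs, nor for its share at resolution 0.5, so these gave no value. Depth limits the endothelial-like, SMC-like, platelet-like and B cell-like values most. The cause of the following moves was not tested.

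Gsdme stood at 0.617 as a mean over cells and 0.737 thinned. The cycling ratio in fibroblast-like cells was 1.49 at 1 gene or more and 2.41 unthinned. Share ratios were 1.26 for monocyte-like cells at 1000 UMIs, 0.676 for cluster 2 at most 10% mitochondrial, and, with each library clustered on its own, 3.60 for SMC-like cells and 0 for cluster 7, as no Gsdme-KO cluster had most of its cells from it. MHC class II in monocyte-like cells was 0.63 at resolution 2, 0.79 with TMM, 0.36 at 1000 UMIs, 0.28 at 10% mitochondrial, 0.81 with doublets kept, 0.58 as a mean over cells, 0.80 with size factors and 0.50 thinned. In fibroblast-like cells, in the order TMM, size factors, mean over cells, thinned, MHC class I was -0.52, -0.53, -0.56, -0.50, complement -0.26, -0.26, -0.36, -0.26, elastic fibre 0.44, 0.43, 0.23, 0.23 and interferon gamma -0.34, -0.35, -0.60, -0.65. Type I interferon in them was -0.18 with TMM and -0.19 with size factors, and complement -0.52 without top doublet scores. Type I interferon in cluster 3 was -0.55 with TMM, -0.56 with size factors, -0.70 at 1000 UMIs and -0.53 thinned, in neutrophil-like cells -0.54 at 1000 UMIs and in dendritic-like cells -0.95 thinned. Chemokines in cluster 3 were 0.48 at 10% mitochondrial and 0.25 without floors. In SMC-like cells the contractile list was 0.18 as a mean over cells and 0.33 thinned, and collagens -0.38 and -0.48.

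Reversed lists at 1000 UMIs were chemokines (-0.051) and T cell activation (-0.18) in monocyte-like cells, and at 10% mitochondrial the lipid-associated list in endothelial-like cells (-0.067). As a mean over cells they were cell cycle in SMC-like (-0.14), complement in endothelial-like (0.37) and resident-type macrophage in T cell-like cells (0.10). Without floors they were alternative activation in SMC-like cells (0.37) and in cluster 7 (0.14). Thinned, they were SMC modulation in B cell-like (-0.090) and endothelial-like cells (-0.16), cell cycle in B cell-like (0.22) and SMC-like cells (-0.42), complement in B cell-like (-0.039), endothelial-like (0.11) and neutrophil-like cells (-0.018), hypoxia in cluster 3 (-0.084) and the unfolded protein response in T cell-like cells (0.062), and the genes Saa3 (-0.31) and Slit2 (-0.016) in endothelial-like cells. Without top doublet scores they were, in T cell-like cells, MHC class II (0.13), alternative activation (0.16), complement (0.55), inflammatory macrophage (0.22), lipid-associated (0.38) and resident-type macrophage (0.59), in platelet-like cells heat shock (-0.40) and Hspa1b (-0.68), and in endothelial-like cells Slpi (-0.42).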

Other observations

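The test of neighbouring genes and the choice of genes near Gsdme were made after the results were seen. Several of the genes that differed in every class lie at the ends of the sex chromosomes. Gm15726 lies on X (169979047 to 169985232), antisense within Mid1, so without strand UMIs of the pair cannot be told apart, and it stood at 19.2 CPM in WT and 72.6 CPM in Gsdme-KO over all cells, while Gm47283 (31.1 and 107 CPM) and Gm21860 (9.57 and 37.0 CPM) lie on Y from 90784738 and 90754513. Mid1 was named as higher in Gsdme-KO in monocyte-like and dendritic-like cells and in macrophage clusters 2, 3 and 7, at ratios of 3.61, 3.99, 4.64, 2.86 and 3.30. Vmn2r96, a vomeronasal receptor gene on 17, stood at 28.9 and 0.498 CPM.

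Of 7 measured genes within 1 Mb of Gsdme, 1 differed by over 1.5-fold over all cells: Npy (ratio 0.611, 0.489 to 0.762), which was measured in 1 class only, at a log2 ratio of 0.15 there. Mpp6, whose annotated end overlaps Gsdme, had a ratio of 1.33 (1.27 to 1.39), and Cycs, which encodes cytochrome c, also 1.33 (1.25 to 1.42). Tra2a and Osbpl3 had ratios of 0.858 and 0.880, while the median log2 ratio over classes was -0.18 for Tra2a and 0.13 for Osbpl3.

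Named genes in some places lay next to each other, as Slc22a4, Pdlim4 and Lyrm7 did on 11 (53983123 to 54860916). Of 92 named genes, 21 had another named gene with a different name stem within 1 Mb, against a median of 12 and a highest count of 27 in 1000 random draws from 10423 genes that could have been named. Chance placement was therefore not excluded by the bound set for the test. Blocks of DNA that differ between the mouse lines are a candidate explanation that cannot be told apart from the library with 1 library per group.

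Markers of other classes were seen in many cells. At least 3 macrophage markers were seen in 70.0% of WT and 48.9% of Gsdme-KO fibroblast-like cells, and in 30.9% and 18.8% of neutrophil-like cells. At least 3 fibroblast markers were seen in 68.4% of WT and 55.0% of Gsdme-KO cells of macrophage cluster 2.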
